A study of Mnemiopsis leidyi and Trichoplax adhaerens and Amphimedon queenslandica with 10 samples.

How the data were processed

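The series holds 10 samples from 3 organisms: the sponge Amphimedon queenslandica, the comb jelly Mnemiopsis leidyi and the placozoan Trichoplax adhaerens. The data used here are 4 single-cell RNA-seq libraries, 1 each of adult sponge, sponge larva, adult comb jelly and adult placozoan. Per the labels, 20 to 25 animals were dissociated and pooled for a library, and single cells were sorted by FACS into 384-well plates. They were processed by MARS-seq, a method that barcodes the RNA of each well during reverse transcription, pools the cDNA, amplifies it by in vitro transcription and counts molecules through unique molecular identifiers (UMIs). The other 6 samples are chromatin libraries (iChIP input, H3K4me2 and H3K4me3) made from 200000 cells each of 2 organisms, and they were not analysed here.

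The deposited tables give whole UMI counts per feature and cell, not normalized, and the authors assigned each cell to a numbered metacell, a group of cells with similar counts. Bowtie2, SAMtools and deepTools are named in the submitters' processing notes. The role of each tool, the genome builds, the annotations, the cell filter and the way metacells were computed are not given in the sources used here. All cells in the tables had a metacell, and the metacells were used as deposited, with no further filter on cells. No doublet caller was run: cells were sorted singly into wells, and whether doublets were removed is not given in the sources used here. The cell names carry a 4-digit number and a 3-digit number that runs from 1 to 384. These were read as plate and well, a reading that rests on the names alone.

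The files do not pair feature IDs with gene names, and 0 of the IDs of the 4 tables matched the gene table given with the data, which covers a comb jelly assembly (crg_Mlei_v2). The gene lists and cell type markers chosen before the data were examined could therefore not be computed, and no metacell was given a cell type. The rule for named genes fixed then was to print, without names, at most 2 IDs with the highest and 2 with the lowest ratio for a comparison and the 2 IDs with the highest fold in any metacell of each library, among features with at least 50 UMIs in that metacell. The most abundant features were singled out after their values were seen. Features whose IDs start with Contig or bin_ lie outside the numbered gene models. They were kept in totals.

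UMIs were summed over the cells of each metacell and scaled to 100000. The fold of a feature in a metacell was taken over its median metacell after adding a pseudocount of 10, which sets much of the fold where that median is lower than the pseudocount. Of the IDs printed for their fold, only Aqu2.1.31788_001 and Aqu2.1.25093_001 had a median above it, at 11.7 and 12.6 UMIs per 100000. A feature was called restricted when its highest fold was at least 4 and at most 10% of the metacells, rounded up, reached that fold, among features with at least 50 UMIs in the library and metacells of at least 20 cells. Metacells were joined into groups by average linkage on 1 minus the Pearson correlation of log2 folds, with the tree divided at a distance of 0.7. Both this grouping and the distance were chosen after the data were seen, with several distances viewed. Features per cell were computed as the exact expectation at 300 UMIs per cell, leaving out shallower cells. For adult against larval sponge, UMIs per feature were scaled to CPM of the library total, and log2 ratios were taken with a pseudocount of 1 among features with at least 100 UMIs in both libraries together. Larval and adult metacells were compared by Pearson correlation of log2 folds over features that reached 4-fold in at least 1 metacell of each stage.

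Each group has 1 library, so there is no replicate check, and no p-value was computed from cells. Intervals are exact 95% intervals (Clopper-Pearson for shares, Poisson for counts, conditional binomial for ratios) and cover counting error only. For shares of features they also treat features as independent, which they are not. Total depth was 12843741 UMIs in the adult sponge, 1792991 in the sponge larva, 10802687 in the comb jelly and 2278992 in the placozoan. Adult and larval sponge cells have no plate number in common, so stage and plate cannot be told apart. Correlations across features describe the libraries, since genes are not independent replicates.

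The steps were tested on simulated data, with Poisson counts drawn from each library's own feature means and metacell totals and 200 features raised in 1 metacell each. In the adult sponge, on 12757 features, 20.0% of features raised 8-fold were recovered, and on 12744 features 45.0% of those raised 16-fold. In the sponge larva, on 5074 and 5138 features, the shares were 46.5% at 8-fold and 95.5% at 16-fold. In the comb jelly, on 11370 and 11397 features, they were 14.5% at 8-fold and 40.5% at 16-fold. In the placozoan, on 5119 and 5112 features, they were 37.5% at 8-fold and 86.0% at 16-fold. Of features left unraised, 0 were called in any library, but these had the same mean in all metacells and Poisson noise only. The 0 is therefore not a rate of false calls in the real data, where a few cells can hold most UMIs of a feature. The pseudocount thus hides changes of rare features, most of all in the deep libraries, where more rare features pass 50 UMIs. For adult against larva, on 10787 features, a simulated 2-fold change gave a median log2 ratio of 0.98, and on 10796 features an 8-fold change gave 2.94. All 21 larval metacells simulated from adult ones, on 469 features, matched the adult metacell they were drawn from. They were drawn with Poisson noise and no difference between stages, and their median best r was 0.94, against 0.35 in the data. The simulation therefore does not measure how well real larval metacells are matched.

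The alternatives tried covered cell filters, rarefaction depth, fold and UMI minimums, pseudocounts, scaling, weighting of cells, the kind of correlation and subsets of plates. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.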

Results

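Single-cell transcriptomes were collected from 3 animals of early-branching lineages: a sponge, sampled as adult and as larva, a comb jelly and a placozoan, a flat animal without organs. By its title, the study asks how diverse cell types are in such animals. The tables hold 13814 cells in 174 metacells. The adult sponge library has 3870 cells on 13 plates, with a median of 2649.5 UMIs per cell, and the larval library 1932 cells on 10 plates, with 585.5. The comb jelly library has 4803 cells on 16 plates, with a median of 1468 UMIs per cell, and the placozoan library 3209 cells on 12 plates, with 476. Each group is 1 library with no replicate. At 300 UMIs per cell, the median cell showed 243 features in the adult sponge, 213 in the larva, 189 in the comb jelly and 206 in the placozoan. Without rarefaction these medians were 1268.5, 343, 626 and 273. Cells under 300 UMIs were left out of the rarefied values: 62 in the adult sponge, 530 in the larva, 356 in the comb jelly and 1025 in the placozoan.

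The adult sponge had 52 metacells, which fell into 8 groups by expression. Metacells 1 to 20 formed the largest group, with 34.8% of the cells (95% interval 33.3 to 36.3%). Metacells 27 to 35 and 37 to 40 held 28.2% (26.8 to 29.7%), and metacells 36 and 41 to 52 held 26.4% (25.0 to 27.8%). Cells of metacells 1 to 20 had fewer UMIs than the other cells on all 13 plates, with a median ratio of 0.39, while cells of metacells 27 to 35 and 37 to 40 had more on all 13 plates, with a median ratio of 2.48. Metacells 23, 24, 25 and 26 each stood alone. Metacell 26, with 54 cells, had the lowest best correlation with any other metacell (r = 0.13). It also held both features with the highest fold in the library. Aqu2.1.31788_001 was 485-fold above its median metacell there, at 10524 UMIs per 100000 (10368 to 10681), and 17449 of its 18913 UMIs lay in that metacell. It was seen in 29 of the 54 cells, with up to 1730 UMIs in 1 cell, and in 20.4% of other cells. Aqu2.1.20692_001 was 342-fold above its median, with 94.1% of its UMIs in metacell 26, in 24 of the 54 cells. The share of metacells 1 to 20 ranged from 9.90% to 53.2% between plates.

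The sponge larva had 21 metacells in 7 groups. Metacells 4 to 11 held 27.3% of the cells (25.3 to 29.3%), metacells 12 and 18 to 21 held 24.8% (22.9 to 26.8%), metacells 15 to 17 held 22.6% (20.8 to 24.6%), and metacells 13 and 14 held 16.6% (14.98 to 18.4%). Metacells 1, 2 and 3 each stood alone. Cells of metacells 12 and 18 to 21 had more UMIs than the other cells on all 10 plates, with a median ratio of 2.96, and cells of metacells 4 to 11 had fewer on all 10 plates, with a ratio of 0.53. Aqu2.1.33550_001 was 136-fold above its median metacell in metacell 12, where 43 of 49 cells had it, against 2.71% of other cells. Aqu2.1.25093_001 was 89.7-fold above its median in metacell 13 and reached 4-fold in 4 metacells.

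The comb jelly had 55 metacells in 18 groups, of which 9 were single metacells. That number depends on where the tree is divided, with 28 groups at 0.5 and 13 at 0.8. Metacells 1 to 12 held 23.0% of the cells (21.8 to 24.2%) and metacells 13 to 25 held 21.8% (20.6 to 23.0%). Between plates these shares ran from 13.0% to 35.6% and from 13.8% to 32.1%, and that of metacells 38 to 42 from 1.71% to 18.5%. Metacells 48 to 50, with 6.62% of the cells, had more UMIs than the other cells on all 16 plates, with a median ratio of 2.09. Metacell 31 was shallow, with a median of 213.5 UMIs per cell, as was metacell 53, with 350.5. ML085733a was 311-fold above its median metacell in metacell 51, where 56 of 61 cells had it, against 8.10% of other cells. ML102215a was 295-fold above its median in metacell 37, with 92.7% of its UMIs there, in 27 of 49 cells. Its median metacell had 0.55 UMIs per 100000, so its fold is set largely by the pseudocount. Metacell 51 had the lowest best correlation with any other metacell (r = 0.08).

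The placozoan had 46 metacells in 7 groups, or in 14 with the tree divided at 0.5. Metacells 1 to 15 held 30.2% of the cells (28.6 to 31.8%), metacells 16 to 27 with 42 held 25.5% (24.0 to 27.1%), and metacells 28 to 31 held 12.2% (11.1 to 13.4%). The group of metacells 32 to 35, 40, 41, 43, 44 and 46 held 21.8% (20.4 to 23.3%). Cells of this last group had more UMIs than other cells on only 1 of 12 plates, with a median ratio of 0.68. Tadh_P63942 was 1043-fold above its median metacell in metacell 38, at 15459 UMIs per 100000 (14877 to 16058), with 95.8% of its UMIs there and 29 of 33 cells positive. The feature bin_14394 reached 6273 UMIs per 100000 in metacell 45, but only 4 of 34 cells had it, with up to 261 UMIs in 1 cell. Its median metacell had 0 UMIs, so its fold of 628 is set by the pseudocount. The shares of all 4 groups differed between plates: metacells 1 to 15 ranged from 13.3% to 41.9%, metacells 16 to 27 with 42 from 15.9% to 45.2%, metacells 28 to 31 from 3.45% to 19.4%, and the last group from 13.9% to 31.6%.

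**Figure D1:**
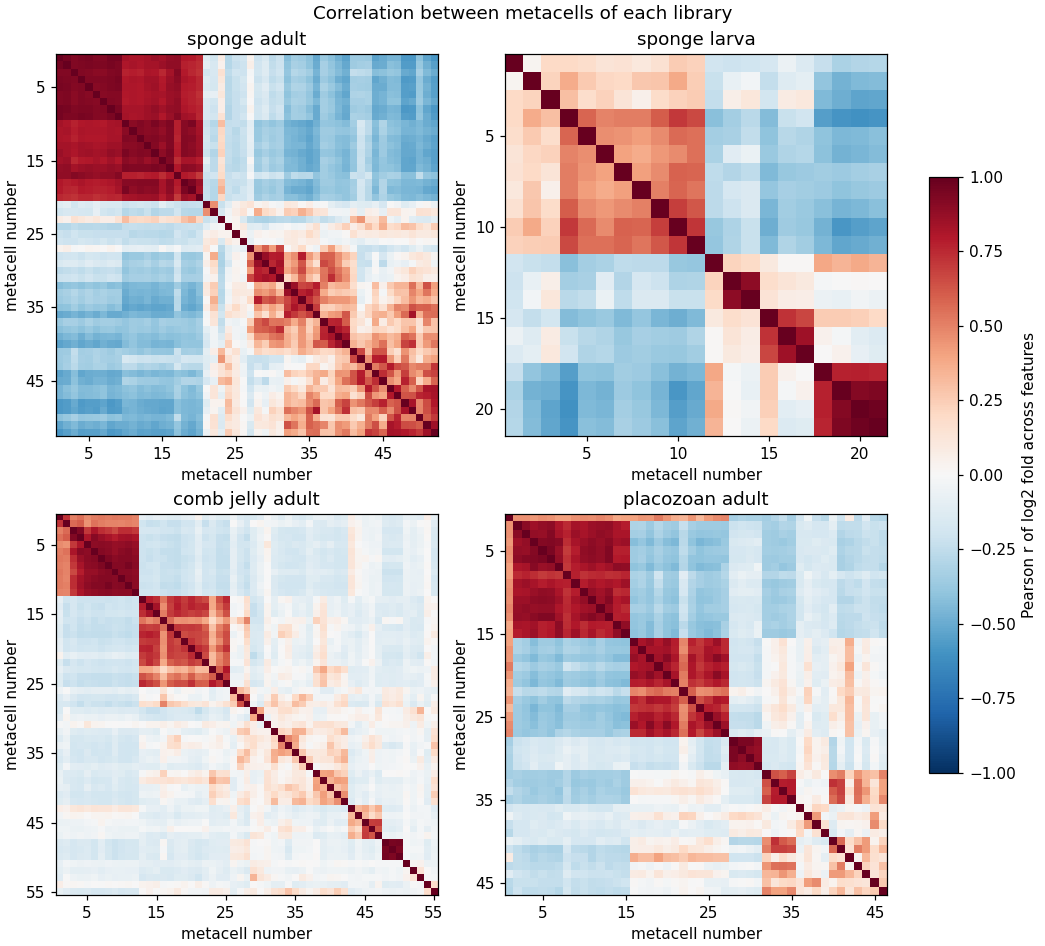
Pearson correlation of log2 fold between all pairs of metacells of a library, with metacell numbers on both axes and colour from blue (negative) to red (positive). The red squares along the diagonal are groups such as metacells 1 to 20 of the adult sponge and 1 to 15 of the placozoan. With the tree divided at 0.7, the comb jelly has 9 metacells that stand alone.

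**Figure D2:**
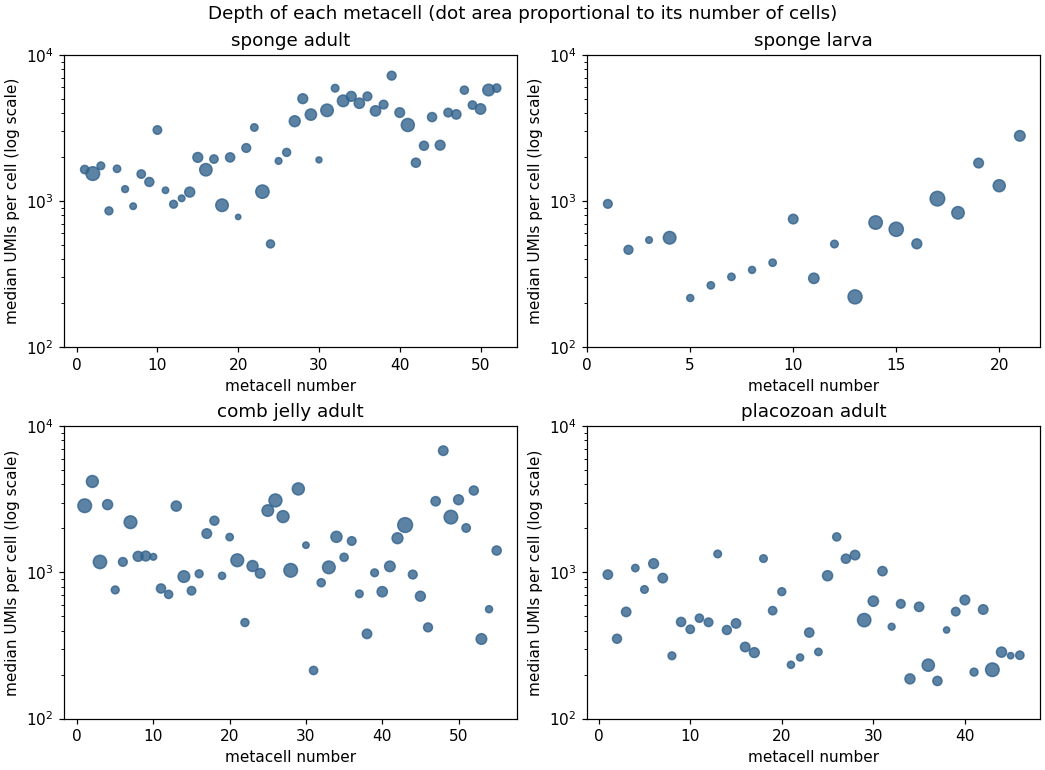
Median UMIs per cell of each metacell on a log axis against its number, with dot area proportional to its number of cells. In the adult sponge, most of metacells 1 to 20 lie below most of metacells 27 to 52, and in the comb jelly metacell 31 is lowest at 213.5.

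Features restricted to few metacells were found in every library. Of features with at least 50 UMIs, 704 of 12749 were restricted in the adult sponge (5.52%, 5.13 to 5.93%), 603 of 5104 in the larva (11.8%, 10.9 to 12.7%), 1834 of 11400 in the comb jelly (16.1%, 15.4 to 16.8%) and 631 of 5109 in the placozoan (12.4%, 11.5 to 13.3%). These intervals treat features as independent, which they are not, and take the metacells as given. In the larva the share was 17.8% on even and 17.1% on odd plates, both above its interval. In any library a subset of plates holds fewer UMIs against the same minimum of 50. Shares on even or odd plates therefore cannot tell a difference between plates from lower depth. In the comb jelly, metacell 50 was the highest metacell of 150 of them and metacell 52 of 162. In the adult sponge, metacells 1 to 20 together were highest for 184, and metacell 21 alone for 96. The order of the libraries depended on the setting. On even plates the share was 18.9% in the comb jelly and 21.3% in the placozoan, and on odd plates 21.9% and 23.3%. The order was also not kept when the size of the libraries was equalised. With 18 metacells of 20 cells and 300 UMIs per cell in each library, over 20 draws, the median share was 21.05% in the adult sponge (range 15.04 to 26.7%), 27.4% in the larva (22.6 to 33.6%), 20.3% in the comb jelly (14.1 to 26.8%) and 14.98% in the placozoan (10.5 to 24.2%), with overlapping ranges. That setting changed cells, UMIs and metacells at once and left 232 to 379 features to test, so the move was not traced to depth alone.

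Fewer features held 50% of the UMIs in the comb jelly and placozoan than in the sponge. In the comb jelly 206 features held 50% of the UMIs, in the placozoan 227, in the larva 388 and in the adult sponge 530. The libraries listed 19636, 14629, 21548 and 29668 features in that order, and no count was made at equal numbers of features. With the mean of per-cell shares the comb jelly (248) and the placozoan (228) changed places. The 10 most abundant features gave another order, with 27.9% of the UMIs in the comb jelly, 16.96% in the larva, 16.5% in the placozoan and 8.13% in the adult sponge. ML12231a alone took 21.02% of comb jelly UMIs, from 10.9% in metacell 49 to 31.6% in metacell 7, and from 12.9% to 30.7% between plates. The comb jelly count of 206 was not computed without this feature. Tadh_P62289, the most abundant placozoan feature, took 5.13%, from 0.27% in metacell 6 to 33.3% in metacell 37, and from 1.09% to 15.7% between plates. Tadh_P63128 took 3.34% and ranged from 0.09% in metacell 6 to 16.3% in metacell 16. Aqu2.1.30623_001 was the most abundant feature of both sponge libraries, with 1.51% of adult and 4.53% of larval UMIs. These 4 features were chosen after their values were seen. UMIs outside gene models made up 2.34% in the adult sponge, 3.60% in the larva, 8.29% in the comb jelly and 10.97% in the placozoan.

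Adult and larval sponge shared 20034 features, of which 10544 had at least 100 UMIs. Aqu2.1.40698_001 had 3093 adult UMIs and 0 larval UMIs, at least 144-fold higher in the adult against a floor of 3 counts in the larval library. Aqu2.1.22934_001 had 2240 and 0, at least 104-fold higher. Aqu2.1.43861_001 had 17 adult and 1181 larval UMIs, 498-fold higher in the larva (309 to 857), and Aqu2.1.27554_001 had 17 and 1045, 440-fold higher (274 to 759). In the larva, 72.9% of the UMIs of Aqu2.1.27554_001 lay in metacell 2, while those of Aqu2.1.43861_001 were spread more widely, with 28.9% in metacell 4. The median log2 ratio of adult over larva was 0.33, with the middle 50% of features between −0.40 and 1.04, and the direction of that median turned when features with few UMIs were kept. The adult library holds 7.16 UMIs per larval UMI, so a minimum on their sum is met more easily by features high in the adult. With the adult library thinned to the larval total, the median was 0.21. Features outside gene models (152 Contig features) had a median of 0.41, at the 24.6th percentile of 10000 random lists matched on mean expression. Across features, which are not independent replicates, r between the stages was 0.59, against 0.98 between even and odd plates within the adult and 0.95 within the larva. After the adult library was thinned to the larval total, with 5513 features left, r between the stages was 0.33. That value covers only features that still had at least 100 UMIs, and r within a stage was not computed on them. Without thinning, r was 0.71 at a minimum of 20 UMIs and 0.79 at 1 UMI, so it moves with the filter. The fall to 0.33 therefore does not show that the stages are less alike at equal depth. The adult table has 9634 features that the larval table lacks and the larval table has 1514 that the adult table lacks, and these were left out.

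Some larval metacells resembled adult ones, and others had a low r with every adult metacell. Over 159 features, larval metacell 18 was closest to adult metacell 22 (r = 0.67), as were metacells 21 (r = 0.66) and 20 (r = 0.57), and larval metacell 19 was closest to adult metacell 34 (r = 0.58). Larval metacells 13 (r = 0.62) and 14 (r = 0.56) were closest to adult metacell 26, and larval metacell 1 to adult metacell 21 (r = 0.54). These 7 of 21 larval metacells held 42.2% of the larval cells. Larval metacells 15 to 17 were closest to adult metacells 43 and 44, at r of 0.45 to 0.50. Larval metacells 4 to 11 reached at most 0.35, and adult metacells 1 to 20 at most 0.33 with any larval metacell. Random equal splits of a metacell's own cells gave a median r of 0.81 in the larva and 0.91 in the adult. In larval metacells 3 and 5 to 9 that r was only 0.43 to 0.53, which limits the r they can reach with an adult metacell. The highest r over 1000 shuffles of the features was 0.42, and 10 larval metacells exceeded their own highest shuffle. The shuffles treat features as independent, which they are not, so their range may be too narrow and the 10 is description only. The count of 7 at r of at least 0.5 fell to 0 with Spearman correlation and to 4 with features at 2-fold, so it is not a number of shared cell types. The partners also changed: with features at 2-fold, larval metacells 18, 20 and 21 were closest to adult metacells 28, 33 and 34, and over the 5 alternatives between 9 and 15 of the 21 larval metacells kept their closest adult metacell.

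**Figure D3:**
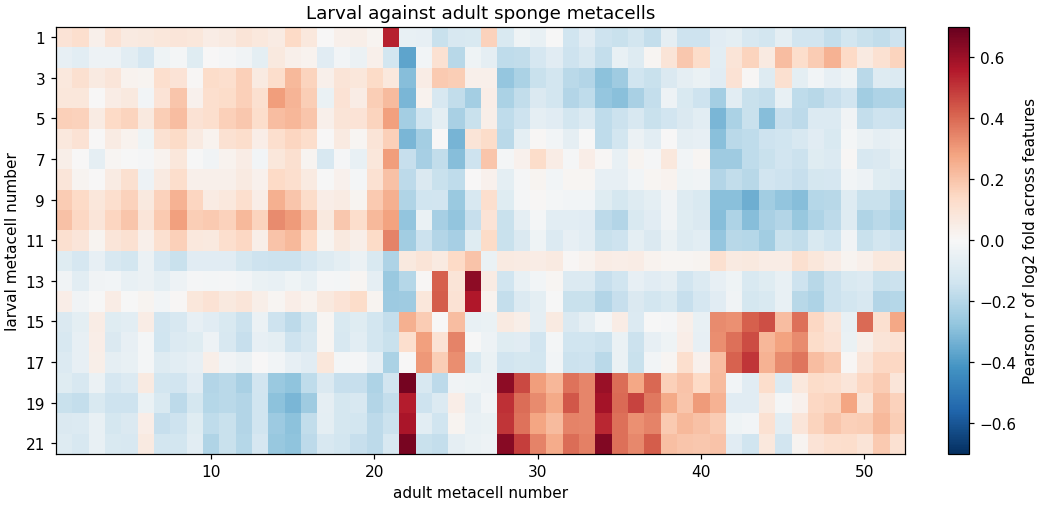
Pearson correlation of log2 fold across 159 features between each larval metacell (rows) and each adult metacell (columns), with colour from blue (negative) to red (positive). Larval metacells 18 to 21 are reddest at adult metacells 22, 28 and 34, and larval metacells 13 and 14 at adult metacell 26.

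**Figure D4:**
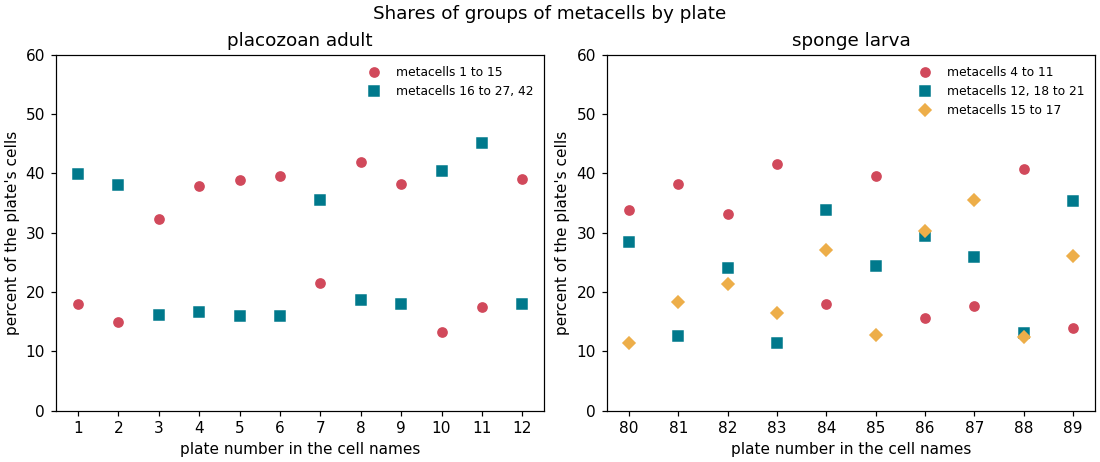
Percent of a plate's cells in groups of metacells, by plate number in the cell names, for the placozoan (left) and the sponge larva (right), with 1 point per plate and group. On the placozoan plates metacells 1 to 15 range from 13.3% to 41.9%, and on the larval plates metacells 4 to 11 range from 14.0% to 41.5%.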

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

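The subsets of plates, the thinning of the adult sponge library, the removal of the limit on the number of metacells and all groupings of metacells were chosen after seeing the data; the other alternatives were fixed before the data were examined. No paired analysis was possible because each group has 1 library, so no groups share more than 1 replicate number. Of 169 alternative values, 80 stayed within the spread set for them, 88 moved and 1 changed sign, and the cause was not tested except where named. The spread was the counting interval of a share, 1.5 times a count, or 0.5 for the log2 ratio of a single ID. For a correlation or median it was the larger shift on even or odd plates, which those plates meet by construction. The bounds for a single ID and for a correlation or median were chosen after seeing the data. Part of the 80 could not move, so their number does not measure stability. Taking every cell or all metacells repeated the main setting. Setting the median ratio to 0 cannot change r, and a UMI minimum does not enter the ratio of a single ID. In the order adult sponge, larva, comb jelly and placozoan, median features per cell were 132, 118, 104 and 114 at 150 UMIs and 437, 377, 331 and 363 at 600 UMIs, and without thinning 1268.5, 343 and 626 in the first 3. The percent of features restricted, in the same order, was 20.8, 47.8, 39.7 and 56.4 at a fold of 2, and 1.96, 3.76, 7.78 and 5.52 at a fold of 8. It was 2.46, 3.03, 9.52 and 5.62 for features with at least 1 UMI, 4.42, 7.56, 13.0 and 9.002 at 20 UMIs, and 7.84, 27.5, 23.8 and 18.7 at 200 UMIs. With a pseudocount of 2 it was 19.1, 37.4, 41.8 and 37.9, and with 50 it was 1.255, 2.51, 4.45 and 3.76. At equal cells, UMIs and metacells it was 21.05, 27.4, 20.3 and 14.98. On even plates it was 6.72, 17.8, 18.9 and 21.3, and on odd plates 17.1 in the larva, 21.9 in the comb jelly and 23.3 in the placozoan. With metacells of at least 50 cells it was 4.87 in the adult sponge, 8.92 in the larva and 14.4 in the comb jelly. With any number of metacells it was 7.01 in the adult sponge, 17.3 in the comb jelly and 14.7 in the placozoan. The adult sponge had the lowest share at every fold, UMI minimum and pseudocount tried, but not at equal cells, UMIs and metacells, and the other 3 libraries changed places. With the tree divided at 0.5, the comb jelly had 28 groups of metacells and the placozoan 14. Between adult and larval sponge, r across features and the median log2 ratio were 0.57 and 0.37 with the mean of per-cell shares, and 0.55 and 0.44 with equal weight per metacell. They were 0.66 and 0.23 at a pseudocount of 10, 0.71 and 0.18 for features with at least 20 UMIs, and 0.79 and −0.10 for features with at least 1 UMI, so the sign of the median depends on the filter. After the adult library was thinned to the larval total they were 0.33 and 0.21, over the features that still had at least 100 UMIs. Scaling without the 50 most abundant features gave a median of 0.13, and a pseudocount of 0.1 gave an r of 0.56. The 4 IDs named for that comparison kept their direction under every alternative. They were picked as the most extreme ratios of the same data, so these alternatives could hardly turn them. The number of larval metacells with an adult match at r of at least 0.5 was 0 with Spearman correlation and 4 with features at 2-fold, and between 5 and 7 otherwise. Gene lists across metacells, and the list part of the comparison of stages, were not run because the files pair no names with the IDs.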

Other observations

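The tests of chance pairing, of leak between wells, of plate depth, of cell depth and of a single population split by plate, including their bounds, were chosen or changed only after related values were seen. The split of transcripts and the share of misassigned cells were given bounds before their values were seen, but the choice to give the latter for each library, and the comparison of splits with the highest shuffle, came afterwards. All 3 patterns were found in the same data they were tested on.

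Groups of metacells also differed between larval sponge plates. On plates 84, 86, 87 and 89, metacells 4 to 11 held 14.0% to 17.9% of the cells and metacells 15 to 17 held 26.0% to 35.6%, and on the other 6 plates 33.1% to 41.5% and 11.5% to 21.4%. Those 4 plates also held more cells, 215 to 251 against 148 to 183.

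Gene models with consecutive numbers shared expression across metacells: in the adult sponge, 40.3% of 917 consecutive pairs had r over 0.5, and the share fell with distance in number, to 32.1% at 2, 24.6% at 3 and 17.1% at 10. Shuffling the numbers 200 times gave at most 20.6%, which argues against chance pairing, and the shares were also above their shuffles in the larva (29.8%, at most 15.9%), the comb jelly (19.0%, at most 5.77%) and the placozoan (14.96%, at most 7.81%). Reads of 1 transcript split between models at a fixed ratio would need 57.7% of the 370 pairs in the adult sponge to have a constant split, and 28.9% had one (24.3 to 33.8%), against 45.2% (38.4 to 52.0%) of a needed 55.7% in the larva, 43.0% (37.1 to 49.0%) of 76.6% in the comb jelly and 53.7% (41.1 to 66.0%) of 68.1% in the placozoan, so such splits may account for part of the excess. Against the highest shuffle in place of the mean, the needed share was 48.9% in the adult sponge and 69.7% in the comb jelly, above the intervals. It was 46.5% in the larva and 47.8% in the placozoan, where splits were not shown to fall short. A split was called constant at a chi-square per degree of freedom of 2 or less over metacell UMIs. Small deviations pass that bound more easily at few UMIs, and the adult sponge and comb jelly were the deepest libraries. Whether splits fall short there cannot be told apart from depth. Reads shared between similar gene copies, a split that varies between cells and shared regulation of neighbours stay open, since neither the sequences nor the positions behind the numbers were used here, and no biological explanation was tested.

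For a subset of restricted features, UMIs outside the metacells that expressed them followed the plate in 3 libraries. The subset, chosen after the data were seen, reached 16-fold in a metacell with at least 500 UMIs there and 4-fold in at most 3 metacells. It had at least 30 UMIs outside, that is in metacells under a fold of 2. The inside level was the feature's UMIs in expressing cells over all UMIs of the plate, so it also rises with the number of such cells. The outside level was its UMIs in the other cells over the UMIs of those cells. The median rank correlation of these levels over plates was 0.49 in the adult sponge (34 features), 0.52 in the comb jelly (186 features) and 0.70 in the placozoan (23 features). These values lay above the highest of 200 shuffles (0.37, 0.17 and 0.25), as leak of molecules between wells of a plate would give. Plates also differed in their shares of groups of metacells, which enters both levels. Shuffling the plates cannot tell leak from such differences between plates, in the placozoan as in the other libraries. In the larva it was −0.036 over 6 features, within its shuffles, so leak was not seen there. Misassigned cells or doublets would place outside UMIs in cells rich in the feature, and the median share in such cells was 8.57% in the placozoan, which argues against them there, but 25.7% in the adult sponge and 26.6% in the comb jelly, where misassignment and leak cannot be told apart, and 26.3% in the larva, where misassignment stays open. A low level of such a feature outside its metacell may therefore not be expression, and no biological explanation was tested.

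On placozoan plates 1, 2, 7, 10 and 11, metacells 1 to 15 held 13.3% to 21.5% of the cells, metacells 16 to 27 held 33.1% to 39.5%, metacells 28 to 31 held 3.45% to 6.88% and the group of metacells 32 to 35, 40, 41, 43, 44 and 46 held 24.8% to 31.6%, against 32.3% to 41.9%, 13.5% to 17.98%, 15.3% to 19.4% and 13.9% to 21.5% on the other 7 plates. The plates were divided at the widest gap in the share of metacells 1 to 15. Among cells of at least 250 and under 600 UMIs these shares still stood 10.4 percentage points apart. That argues only against an effect of a cell's UMIs that is the same on every plate. An effect that differs between plates, or UMIs that differ within that range, could leave such a gap and stay open. Depth of a plate stays open, because the 5 plates had the lowest median UMIs (193 to 407 against 427.5 to 732) and the UMI ratio of metacells 16 to 27 over 1 to 15, with a median of 1.21 that met the bound first set against it, was under 1 on the same 5 plates; against it, plates 10 and 9 had 407 and 427.5 UMIs but 13.3% and 38.3% of cells in metacells 1 to 15, a single pair of plates. A single population split in 2 by plate would not move metacells 28 to 31, so it does not give the whole difference, and for metacells 1 to 15 and 16 to 27 it stays open, since the median r of 0.84 between plates for their log2 ratio follows at least in part from metacells made from the same counts, and the 0.25 for metacells 1 to 15 divided along their first principal component comes from fewer cells of 1 group. Sorting from different pools or gates stays open, as 0 plates have a pool or gate named in the sources used here, and a difference between the animals pooled was not tested.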
